A study of Homo sapiens with 12 samples.

How the data were processed

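RNA from RD cells, a line derived from an embryonal rhabdomyosarcoma, was measured on 12 Affymetrix U133A arrays, 1 per sample, in 4 groups of 3. The labels gave each sample its construct, its treatment and a replicate number. The design text speaks of 3 populations of cells for each construct; the labels do not say whether the replicate number marks a population.

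The deposited values were probe set signals on a linear intensity scale. They were made with GCOS and MAS5, per the submitters' processing notes, with no version given there. In the table the trimmed mean of the signal was nearly the same on every array, as scaling to a common target leaves it. Per the labels' protocols, total RNA was extracted with a column kit and labelled with biotin by the array maker's standard procedure. The signals were not scaled again before testing, and a change in total RNA per cell would therefore be invisible. No detection calls were used here. The deposited intensity table held 22283 probe sets, of which 68 were controls and were left out of every test. Of the other 22215 probe sets, 19065 had 1 gene symbol in the array annotation, 1043 had several and 2107 had none; only probe sets with 1 symbol were named. Symbols were looked up by Entrez identifier in a RefSeq gene table of assembly GRCh38, which altered 0 of them. No genome sequence was used here, so no positions are given.

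Signals were transformed as log2(signal + 16), and every fold change is on that scale, which understates the change of dim genes. The 40% of probe sets with the lowest mean signal over the 12 arrays, those under 36.7, were left out, which left 13329 probe sets and 8124 genes. Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). The 5 contrasts were 4-OHT in cells labelled PAX3-FKHR-ER, 4-OHT in cells labelled pK1, the difference of those changes, and the constructs against each other without and with 4-OHT. Tests were two-sided, and the Benjamini-Hochberg adjusted p was held against 0.05 within each contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

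Of 23 gene lists written from general knowledge, 22 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, the one of highest mean signal, and adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list moves on balance 1 way, were run beside it. The list called PAX3-FKHR targets was drawn from general knowledge of this fusion, so its direction is not independent of earlier studies of it.

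The groups, the fit, the filter, the lists, 22 alternatives and the rule for named genes were fixed before the data were examined. The alternatives were 10 other settings and the omission of each of the 12 arrays in turn. That rule took, for 4-OHT in cells labelled PAX3-FKHR-ER, the 10 genes each way with the largest change among those past the threshold with no overlap between the groups, or the 5 each way with the smallest p where none passed. The other contrasts took 5 each way. It added up to 4 members of each list described, and always PAX3, FOXO1, ESR1, MYCN, FGFR4, MYOD1, MYOG and CDH3 by their brightest probe set. CDH3 lay under the signal filter and was not tested.

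Whether the replicate numbers pair the samples was checked by a fixed rule, that every correlation between same-numbered samples exceed 0.1. Deviations from the group means correlated between same-numbered samples over all tested probe sets, with r = 0.85, 0.70 and 0.71 for the cells labelled PAX3-FKHR-ER with and without 4-OHT and 0.79, 0.79 and 0.82 for pK1. Between constructs r was 0.69, 0.15 and 0.46 without 4-OHT and 0.57, 0.18 and 0.35 with it. The numbers were therefore taken to pair the samples, and fits with the replicate as a block (the pair of arrays sharing construct and number for 4-OHT, the number for the constructs) are given where they changed a call. The rule compared no samples of different number, and with replicate 1 apart it could pass whatever the numbering of the rest. For 4-OHT, log2 signals of PAX3-FKHR-ER replicates 2 and 3 correlated at 0.96 and 0.97 by number, and 0.931 and 0.942 across numbers. Between constructs without 4-OHT, PAX3-FKHR-ER replicate 2 correlated at 0.875 with pK1 replicate 2 and 0.914 with 3. Replicate 3 had 0.942 with pK1 replicate 3 and 0.899 with 2. So pairing of constructs by number was not shown.

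A further fit was chosen after the data had been seen. It used the 8 arrays of replicates 2 and 3, without and with the block. It was added once the replicate 1 arrays had been found to lack poly-A spike-in signal, with some construct probe sets against their labels, and after the fits to 12 arrays had given 0 probe sets past the threshold. The block left 2 residual degrees of freedom for the 4-OHT contrasts, so much of its estimate of spread was borrowed across probe sets. The rule for named genes was applied to it with 2 arrays per group. No sample was given another label.

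The test was run on simulated data for 4-OHT in cells labelled PAX3-FKHR-ER, with 13329 probe sets, 200 of them changed, in 5 runs. The fit to 12 arrays recovered 22.4% of 2-fold and 72.4% of 4-fold changes with 0.4 false calls per run. With the block it recovered 65.8% and 95.6% with 7.2 false calls. The fit to 8 arrays with the block recovered 17.2% and 75.4% with 1.4 false calls. The simulated change was put on all 3 arrays labelled PAX3-FKHR-ER with 4-OHT. Population effects were drawn apart for each construct and number, and noise apart for each probe set. In the data replicate 1 stood apart under both labels, and its PAX3-FKHR-ER pair showed little of the response of replicates 2 and 3. These rates therefore need not hold for the data. Array number, at 3 or 2 per group, limits the precision throughout, and limma p-values measure the spread between these samples. Camera at the preset correlation sets the genes of a list against the other genes and takes them as nearly independent. Its p-values therefore do not measure the spread between samples, however small they are.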

Results

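The series asked which genes the fusion transcription factor PAX3-FKHR regulates in rhabdomyosarcoma cells. PAX3-FKHR joins the DNA-binding part of PAX3 to FKHR (now FOXO1) and marks alveolar rhabdomyosarcoma. RD cells come from the embryonal form of the tumour. They carried either PAX3-FKHR-ER, the fusion joined to a modified estrogen receptor ligand-binding domain that 4-hydroxytamoxifen (4-OHT) activates, or the empty vector pK1. Each was kept without 4-OHT or given 30 nM for 24 h. There were 3 arrays in each of the 4 groups. The median probe set signal lay between 50.4 and 62.8 on the 12 arrays.

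Spike-in signal was missing on the arrays of replicate 1. The 24 poly-A control probe sets, which read RNA spiked in before labelling, had median signals of 118 to 291 on the 8 arrays of replicates 2 and 3, but 2.58 to 7.41 on the 4 arrays of replicate 1. Those 4 arrays also stood apart over all tested probe sets: Pearson r of the log2 signals was 0.957 to 0.982 among them and 0.815 to 0.869 between them and the other 8, which correlated at 0.867 to 0.982 with each other. Probe sets of genes in the construct that were higher under the fusion label in replicates 2 and 3 without 4-OHT were mostly not so on those arrays, and some other probe sets of the same genes did not separate the constructs. FGFR4, a receptor known as a direct target of the fusion, read 479 and 483 on the arrays labelled PAX3-FKHR-ER without 4-OHT in replicates 2 and 3 against 89.8 and 190 on those labelled pK1, while in replicate 1 it read 509 and 551. FOXO1 was 135 ± 15.9 against 44.1 ± 11.4 (SD, n = 2) in replicates 2 and 3 without 4-OHT, and 142 against 214 in replicate 1. PAX3 was 102 ± 4.58 against 36.0 ± 7.68 (SD, n = 2), and 17.6 against 49.4 in replicate 1. With 4-OHT, FOXO1 was at 138 against 121 and PAX3 at 58.9 against 57.8 in replicate 1. A second FOXO1 probe set was higher under the fusion label there, at 313 against 198 without and 257 against 69.5 with 4-OHT, but in replicates 2 and 3 without 4-OHT it read 59.9 and 19.7 against 61.5 and 48.4. For ESR1, the probe set named by the rule read 66.7 and 30.6 against 41.3 and 43.9 in replicates 2 and 3 without 4-OHT, and 29.4 against 63.2 in replicate 1. Another ESR1 probe set read 121 and 76.2 against 4.16 and 12.7 without and 58.6 and 39.2 against 5.05 and 5.78 with 4-OHT in replicates 2 and 3, but 7.5 against 57.0 and 44.7 against 58.4 in replicate 1. Under the signal filter, further ESR1 probe sets read 53.1 and 68.3 against 8.29 and 7.48, and 72.3 and 31.2 against 9.44 and 9.1, without 4-OHT in replicates 2 and 3. In replicate 1 they read 5.67 against 22.7 and 8.89 against 36.1. Not all ESR1 probe sets did so, as a tested one read 55.9 and 28.1 against 43.3 and 33.8 in replicates 2 and 3. These probe sets may also read the cells' own transcripts or lie outside the construct, so they do not settle the labels. Samples are therefore named by their labels, and every direction taken from all 12 arrays rests on the labels of replicate 1.

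Across all 12 arrays, genes of muscle contraction and differentiation were lower with 4-OHT in cells labelled PAX3-FKHR-ER, with a median log2 change of -0.35 over 29 genes, 24 of them negative. Known targets of the fusion were higher, with a median of 0.32 over 26 genes, 20 of them positive. Camera gave adjusted p = 0.000922 for the muscle list and 0.00204 for the targets, and both calls were lost at adjusted p = 0.983 with an estimated correlation. The residuals behind that estimate hold the offset of the replicate 1 arrays, which can raise it. In the paired fit to replicates 2 and 3 it rests on 2 residual degrees of freedom. A list call lost with it, here or below, is thus left undecided and is not shown to be false. The muscle call ended without PAX3-FKHR-ER without 4-OHT replicate 2 (adjusted p = 0.447) or 3 (0.0616) or with 4-OHT replicate 1 (0.229), and the target call without PAX3-FKHR-ER with 4-OHT replicate 2 (0.257) or without 4-OHT replicate 1 (0.193). With the replicate block, the interferon response list (median -0.26, adjusted p = 7.98e-05) and the myogenic regulators (median -0.24, adjusted p = 0.015) were lower too, each with adjusted p = 0.532 with an estimated correlation.

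No single gene passed in that comparison. The fit to 12 arrays gave 0 of 13329 probe sets with an adjusted p under 0.05 in limma, and 62 with an unadjusted p under 0.05, where chance alone gives about 666. The block gave 0 and 894. Without the block, the spread shared within pairs stays in the residual, so p-values of the 12-array fits run too large. The order of genes by smallest p below rests on them. The smallest p among higher genes belonged to IL11, an interleukin (log2 0.98 ± 0.27 SE, adjusted p = 1), followed by MYO15B, TPST2, UBOX5 and NRG1. Among lower genes it belonged to CIITA, a coactivator of MHC class II genes (-1.07 ± 0.30 SE, adjusted p = 1), followed by PSMD9, DYRK3, GPSM2 and TRIM14. In the muscle list MB, which encodes myoglobin, had the smallest p (52.4 ± 3.63 with and 86.7 ± 6.06 without 4-OHT, SD, n = 3, log2 -0.59, adjusted p = 1 in limma), followed by TNNT3, MYH7 and MYBPH. In the target list FOXF1 (0.48), POU4F1 (0.89), MYOG (-1.42) and CXCR4 (1.40) came first. MYCN (0.95), MYOD1 (0.48), FGFR4 (-0.19), PAX3 (0.21), FOXO1 (-0.43) and ESR1 (0.15) did not pass either.

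**Figure D1:**
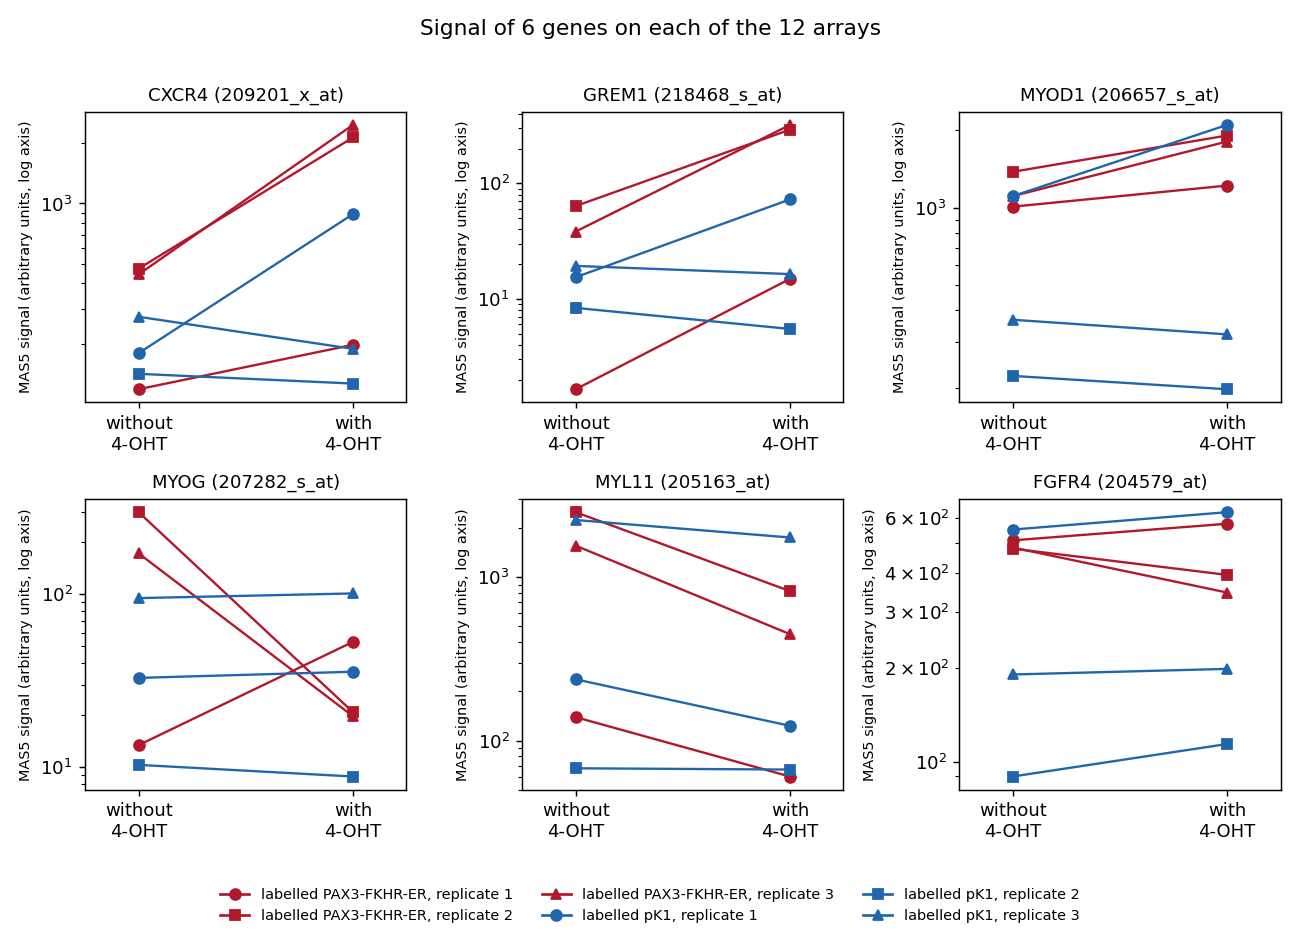
MAS5 signal (arbitrary units, log axis) of CXCR4, GREM1, MYOD1, MYOG, MYL11 and FGFR4 on each of the 12 arrays, with a line joining the arrays without and with 4-OHT that share a construct label and a replicate number. In replicates 2 and 3 labelled PAX3-FKHR-ER, CXCR4 went from 474 and 444 to 2130 and 2460, and in replicate 1 it went from 180 to 885 on the arrays labelled pK1 and from 119 to 198 on those labelled PAX3-FKHR-ER.

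In replicates 2 and 3 alone, fitted as pairs, 4-OHT lowered myogenin (MYOG), a regulator of terminal muscle differentiation, from 235 ± 89.6 to 20.3 ± 0.745 in cells labelled PAX3-FKHR-ER (SD, n = 2; log2 -2.74 ± 0.25 SE, limma adjusted p = 0.00327). It read 52.6 ± 59.8 and 55.0 ± 65.3 in those labelled pK1, and in the replicate 1 pair labelled PAX3-FKHR-ER it went the other way, from 13.4 to 53 (log2 1.23). Muscle genes fell with it in the PAX3-FKHR-ER pairs of replicates 2 and 3: MYBPH, a myosin-binding protein (-2.23), CKM, muscle creatine kinase (-1.75), MYL11, a fast-muscle myosin light chain (-1.68), MYH3, embryonic myosin heavy chain (-1.55), and TNNC2, fast troponin C (-1.21). The chemokine receptor CXCR4 rose from 459 ± 21.3 to 2290 ± 236 (log2 2.28 ± 0.14 SE, limma adjusted p = 0.0011), and all 3 of its probe sets passed. GREM1, a secreted BMP antagonist, rose by 2.29 ± 0.26 SE (limma adjusted p = 0.00808), and POU4F1, a POU-domain transcription factor, by 1.58 ± 0.23 SE (limma adjusted p = 0.0156).

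In all, 186 probe sets passed in that paired fit in limma, 106 higher and 80 lower. The other genes that rose most were PLXNC1 (2.14), PDE9A (1.90), ARRB1 (1.81), PRKAR2B (1.77), ING4 (1.70), LDOC1 (1.65) and SYTL2 (1.60); the second probe set of ING4 went the other way, at -0.52, and did not pass. The other genes that fell most were RASSF4 (-1.96), LINC00339 (-1.82), STC1 (-1.74), DUSP4, a MAP kinase phosphatase (-1.68), IQSEC1 (-1.68) and GLRX, glutaredoxin (-1.68). MYOD1 (0.58, limma adjusted p = 0.0625), MYCN (1.27, 0.114), FGFR4 (-0.36, 0.344), FOXO1 (-0.63, 0.285), PAX3 (-0.26, 0.743) and ESR1 (0.18, 0.888) did not pass. This fit was chosen after the 12-array fits had given 0: the same 8 arrays gave 0 without the block (270 at an unadjusted p under 0.05), 17 with no intensity trend, 37 with no signal filter and 536 with only the 2 groups, and 0 when the with and without labels of the replicate 2 pair were turned. Turning 1 of the 2 pairs moves a change shared by both into the residual. That last 0 therefore follows for such probe sets and says little about chance.

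The lists moved in the same paired fit as follows. Of 29 muscle genes 6 fell and 0 rose over all probe sets tested, and 14 fell and 1 rose adjusted over the list alone (median -0.54, camera adjusted p = 4.76e-11). Of 26 fusion targets, 4 rose and 2 fell, MYOG and the Notch effector HEY1 (-1.19), and 12 rose and 4 fell adjusted over the list alone (median 0.39, camera adjusted p = 8.66e-05). Of 20 interferon response genes 1 fell, IFIT1 (-0.95), and 6 fell adjusted over the list alone (median -0.29, camera adjusted p = 7.26e-05). These 3 lists had adjusted p = 0.288 with an estimated correlation, and fry gave adjusted p = 0.0326, 0.00163 and 0.00668. Of 13 myogenic regulators MYOG and ID3 (-0.66) fell, with a median of -0.17 (camera adjusted p = 0.00844, and 0.432 with an estimated correlation). Of 16 Notch and Wnt genes 3 fell, HEY1, FZD2 (-1.0) and WNT5A (-0.95), and 2 rose, among them LGR5 (0.86), with a camera adjusted p = 0.0166, and adjusted p = 0.468 with an estimated correlation. Of 34 cell cycle genes CCNE1, cyclin E1, rose (0.82), with a list median of 0.07 (camera adjusted p = 0.0166, and 0.696 with an estimated correlation). The vector pairs moved much alike for the myogenic regulators and the cell cycle list. In replicates 2 and 3 the myogenic medians were -0.16 and -0.3 labelled PAX3-FKHR-ER and -0.16 and -0.1 labelled pK1. Those of the cell cycle list were 0.12 and 0.05 against 0.01 and 0.07. Neither list was called in the difference between constructs in this fit, so these calls do not set the constructs apart.

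**Figure D2:**
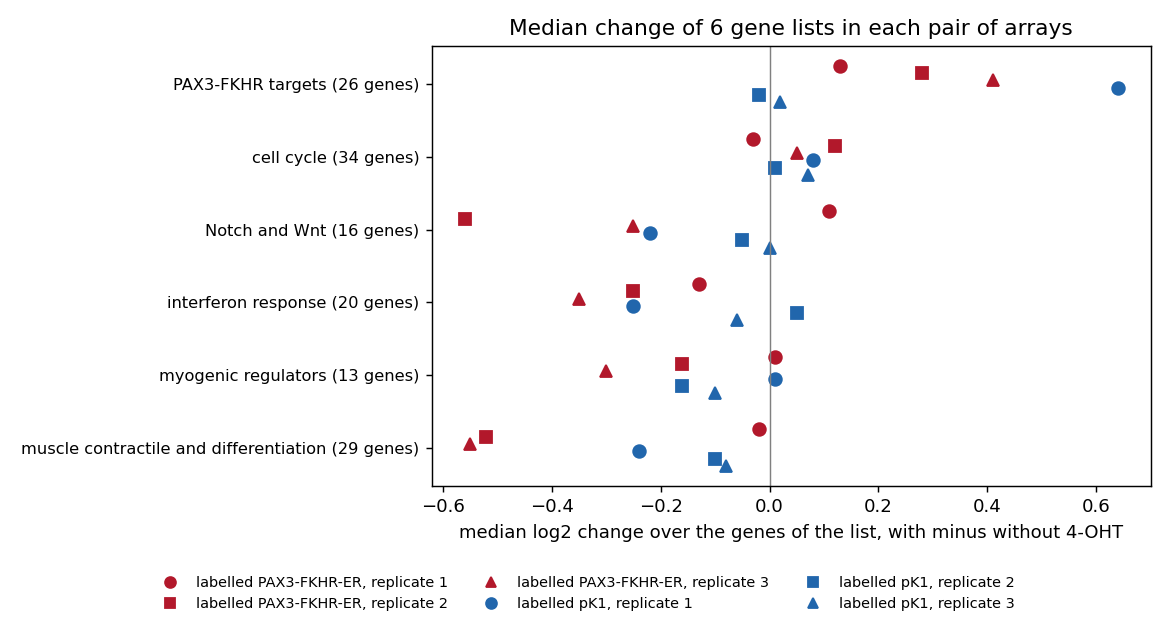
Median log2 change, with minus without 4-OHT, over the measured genes of 6 lists in each of the 6 pairs of arrays, coloured by construct label and marked by replicate. The muscle list lay at -0.52 and -0.55 in replicates 2 and 3 labelled PAX3-FKHR-ER and at -0.02 in replicate 1, and the fusion targets lay at 0.64 in the pair labelled pK1 of replicate 1.

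The vector cells were the control for 4-OHT itself. In cells labelled pK1, 0 of 13329 probe sets passed in limma across 12 arrays, with 72 at an unadjusted p under 0.05, and 0 passed with the block (916) or in replicates 2 and 3 (67, and 760 with the block). ZNF140 (log2 0.67 ± 0.22 SE), PPP3CC, CARS1, PPP1R12A and TOPORS had the smallest p among higher genes. UBE2G2, a ubiquitin-conjugating enzyme (-0.89 ± 0.21 SE), NSG1, RAP1GAP, PATZ1 and HSPB7 had it among lower genes, each with an adjusted p of 1 in limma. In replicates 2 and 3, paired, PTPRO (-1.13) and DBNDD1 (-1.73) came nearest, at a limma adjusted p = 0.706. Muscle genes had a median change of -0.08 across 12 arrays, and MYOG of 0.03. No list passed with camera. Heat shock genes came nearest (median 0.15, adjusted p = 0.0663), and passed with the 60% filter (0.0218), with equal medians (0.0195) and without PAX3-FKHR-ER with 4-OHT replicate 1 (0.0416). With 1 pK1 array left out, 2 to 6 lists passed, the most without pK1 with 4-OHT replicate 3. With the block, heat shock genes and fusion targets (median 0.15) were higher at adjusted p = 0.01, and adjusted p = 0.704 with an estimated correlation. The fusion target call rested on replicate 1, whose pair labelled pK1 had a median of 0.64 against -0.02 and 0.02 in replicates 2 and 3.

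The response to 4-OHT was compared directly between the constructs. In replicates 2 and 3, paired, the change of CXCR4 in cells labelled PAX3-FKHR-ER minus that in cells labelled pK1 was 2.60 ± 0.20 SE on the log2 scale (limma adjusted p = 0.00442). BCHE, butyrylcholinesterase (1.62, 0.0194), and CAV1, caveolin 1 (1.33, 0.0496), also had positive differences. GLRX (-1.98, 0.0130), PLK2, a polo-like kinase (-1.62, 0.0310), and MYL11 (-1.49, 0.0496) had negative ones, by limma adjusted p. MYOG differed by -2.74 but missed the threshold (limma adjusted p = 0.0530). The muscle list (median -0.59, camera adjusted p = 1.46e-05), the fusion targets (0.32, 0.00364), the interferon response (-0.26, 0.00631) and the Notch and Wnt list (-0.24, 0.0359) differed, none of them with an estimated correlation, where the smallest adjusted p was 0.499. Replicate 1, left out of this fit, had CXCR4 in the other order, at 0.66 labelled PAX3-FKHR-ER and 2.2 labelled pK1.

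In that comparison 7 probe sets passed in limma, 4 higher and 3 lower. The same 8 arrays gave 0 without the block (144 at an unadjusted p under 0.05), 0 with no signal filter, 0 with no intensity trend and 0 when the with and without labels of the replicate 2 pair were turned. That last 0 says little about chance, as turning a pair moves a shared change into the residual. Across 12 arrays 0 passed, with 39 at an unadjusted p under 0.05, and with the block 0 passed, with 634. The 12-array values with the smallest p were MYO15B (2.12), UBE2G2 (1.09), IL11 (1.27), TLN1 (0.91) and SOX21 (1.51) among higher genes and KLHL21 (-1.15), MAGOHB (-1.57), MARK4 (-1.28), TRIM14 (-0.83) and RCN1 (-0.82) among lower genes, each with an adjusted p of 1. With the block, the muscle list (median -0.18) and heat shock genes (-0.14) differed at camera adjusted p = 0.0212, and adjusted p = 0.960 with an estimated correlation.

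The constructs were next compared without 4-OHT. Muscle genes (median log2 0.29 over 29 genes, camera adjusted p = 0.00725), fusion targets (0.35 over 26, 0.00952) and myogenic regulators (0.41 over 13, 0.045) were higher in cells labelled PAX3-FKHR-ER across 12 arrays. Ribosomal proteins (0.13 over 17, 0.00725) and heat shock genes (0.15 over 10, 0.0379) were higher as well, but the ribosomal direction turned under quantile normalization. With an estimated correlation the adjusted p was 0.494 for heat shock genes and 0.849 for the other 4 lists. The muscle and target calls ended without pK1 without 4-OHT replicate 2 (camera adjusted p = 0.639 and 0.368). They also ended without PAX3-FKHR-ER without 4-OHT replicate 2 (0.258 and 0.0516). Cholesterol synthesis genes (0.34 over 18) missed the threshold at camera adjusted p = 0.0520 and passed with the block (0.0162, and adjusted p = 0.713 with an estimated correlation). NEB, nebulin (log2 1.35), and TNNT1, slow troponin T (0.81), were among the muscle genes with the smallest p, and TPM1 went the other way (-0.54). FGFR4 (1.13), MYOD1 (1.32) and SKP2 (0.83) led the targets, and MYOD1, MSC, EYA1 and TCF12 the regulators. In replicate 1 FGFR4 (509 against 551) and MYOD1 (1010 against 1110) were not higher under the fusion label. HSPD1 (0.32) and RPL35 (0.29) led their lists. These arrays labelled PAX3-FKHR-ER without 4-OHT also enter the 4-OHT comparison with the opposite sign, so the results of the comparisons are not independent.

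Of single genes, 0 of 13329 passed in limma across 12 arrays (277 at an unadjusted p under 0.05), and 0 with the block (981). PPP3CB (log2 1.17), CFAP70, FNBP1L, MED17 and WDR3 had the smallest p among higher genes, and EPAS1, the hypoxia-inducible factor HIF-2 alpha (-2.18), CHST3, IL11, MAF and LRP10 among lower ones, each with an adjusted p of 1. In replicates 2 and 3, paired, 1 probe set passed in limma: FABP5, a fatty acid binding protein, read 2.72 ± 0.948 against 244 ± 61.2 (SD, n = 2; log2 -3.78 ± 0.27 SE, adjusted p = 0.0356), and 0 passed there with no signal filter or after quantile normalization. The FABP5 signal of 2.72 lay under the amount added before the log transform. The size of its log2 change is thus set largely by that amount and is likely understated. The median of the fusion targets in replicates 2 and 3, paired, was 0.76 (camera adjusted p = 3.5e-08, and 0.837 with an estimated correlation).

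With 4-OHT, fusion targets (median log2 0.44 over 26 genes, camera adjusted p = 0.00121) and cholesterol synthesis genes (0.28 over 18, 0.0296) were higher in cells labelled PAX3-FKHR-ER across 12 arrays, each with adjusted p = 0.817 with an estimated correlation. MET, a receptor tyrosine kinase (1.00), MYOD1 (1.61), POU4F1 (1.02) and CXCR4 (1.62) led the targets, and SREBF2, a regulator of sterol genes (0.66), SC5D (0.65), HMGCS1 (0.66) and MVK (0.32) the cholesterol list. With the block, the interferon response was lower as well (median -0.36, camera adjusted p = 0.00397, and 0.725 with an estimated correlation). The target call ended without replicate 2 of either construct (adjusted p = 0.370 for pK1 and 0.0608 for PAX3-FKHR-ER), and 4 of the 12 arrays each ended the cholesterol call, at up to 0.618.

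Single genes passed only within replicates 2 and 3. Paired, 17 probe sets were higher and 4 lower in limma, and without the block 11 and 2. CXCR4 read 2290 ± 236 against 158 ± 44.1 (SD, n = 2; log2 3.75 ± 0.26 SE, limma adjusted p = 0.0161). GREM1 (3.61), CCNA1, cyclin A1 (3.28), PLXNC1 (2.96) and MYOD1, a master regulator of the muscle lineage (2.80), were also higher, each at a limma adjusted p = 0.0385. FABP5 (-3.68), KCTD12 (-3.22), ANXA4, an annexin (-2.63), and ID1, an inhibitor of differentiation (-1.93), were lower. The mean of the dimmer group was 9.96 for FABP5, 6.57 for ANXA4, 10.9 for GREM1 and 15.7 for CCNA1. These lay under the amount added before the log transform, so the size of those changes is likely understated. Across 12 arrays 0 of 13329 passed in limma (267 at an unadjusted p under 0.05), and 0 with the block (931). LTBP4 (1.32), SLC6A3, OSR2, DBNDD1 and ZNF609 had the smallest p among higher genes there, and CHST3 (-1.44), EPAS1, PAPSS2, SND1 and VAT1 among lower ones.

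RNA quality was read from control probe sets, and no test was made between the groups. The 3-prime over 5-prime ratio of the GAPDH control lay between 0.842 and 1.17, and that of actin between 0.833 and 1.05 on 11 arrays and at 1.62 on pK1 with 4-OHT replicate 2. The 5-prime control probe set of 18S ribosomal RNA read 3175 on PAX3-FKHR-ER with 4-OHT replicate 2 and 548.9 on its partner without 4-OHT, and 97.9 against 208 in replicate 3.

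**Figure D3:**
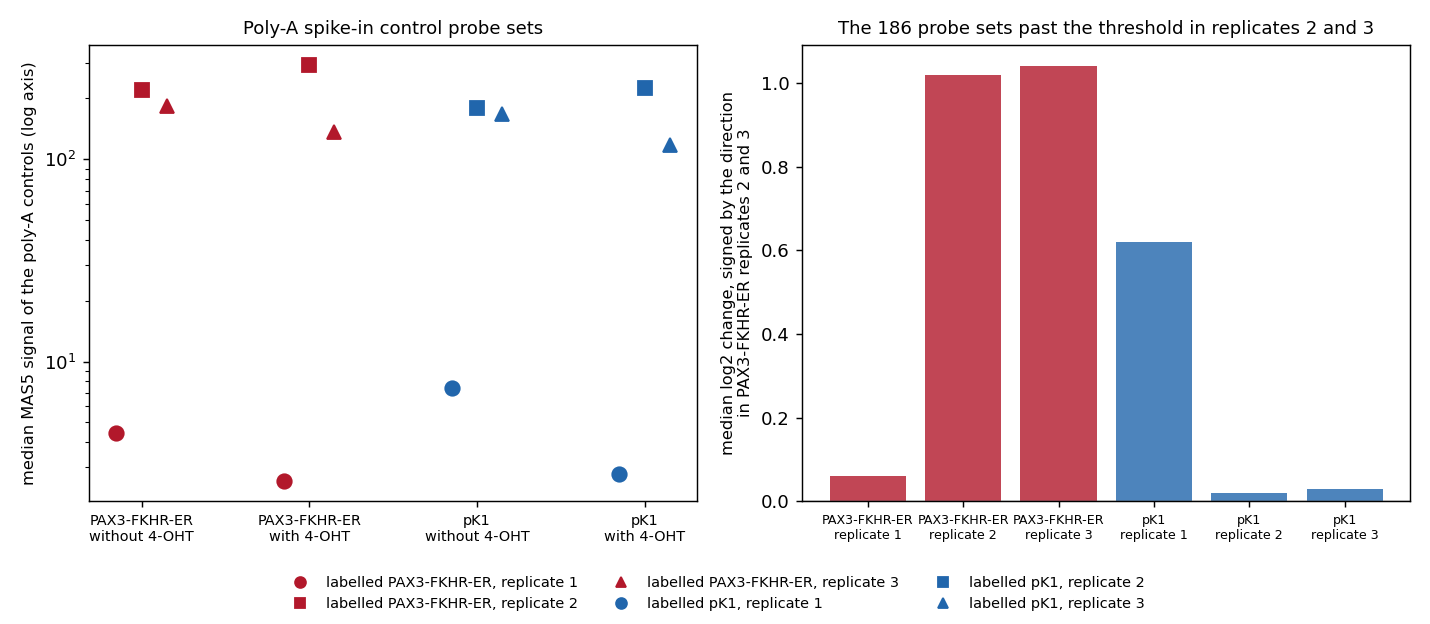
On the left, the median MAS5 signal (log axis) of the 24 poly-A control probe sets on each array, by group, with the marker giving the replicate; on the right, bars of the median log2 change with 4-OHT over the 186 probe sets that passed in replicates 2 and 3 labelled PAX3-FKHR-ER, signed by their direction there, in each pair of arrays. The bars for replicates 2 and 3 labelled PAX3-FKHR-ER are tall by the choice of probe sets; that for replicate 1 labelled pK1 stands at 0.62 and the one labelled PAX3-FKHR-ER at 0.06.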

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

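The fits to replicates 2 and 3, and the tests below of 4-OHT itself and of RNA quality, were chosen only after the results were seen. The tests on replicate 1 were set down before the medians they measure were computed, but after the signals of FGFR4, MYOD1, MYCN, MYOG and ESR1 on each array had been seen; the interval of the percent was added after it was known.

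The response to 4-OHT differed between the constructs by a direct test for 6 genes in replicates 2 and 3, paired. The log2 difference, PAX3-FKHR-ER minus pK1, was 2.60 and 2.45 for 2 probe sets of CXCR4, 1.62 for BCHE and 1.33 for CAV1, and it was -1.98 for GLRX, -1.62 for PLK2 and -1.49 for MYL11. No probe set passed on these arrays without the block, with no signal filter or with no trend. The replicate 1 order was the other way for CXCR4 (0.66 labelled PAX3-FKHR-ER, 2.2 labelled pK1) and GLRX (-0.21 and -0.89). MYL11 was nearly level there (-1.02 and -0.86). Among gene lists in the same fit, camera gave an adjusted p of 1.46e-05 for muscle genes, 0.00364 for fusion targets, 0.00631 for the interferon response and 0.0359 for Notch and Wnt genes. With the block on all 12 arrays it gave 0.0212 for muscle genes and 0.0212 for heat shock genes. None of these list differences held with an estimated correlation.

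A control probe set that enters no comparison stood high on 1 array. The 5-prime probe set of 18S ribosomal RNA read 3175 on PAX3-FKHR-ER with 4-OHT replicate 2, where the next highest array read 548.9 and the lowest 35.67.

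The 4-OHT response of replicates 2 and 3 was weak in the replicate 1 arrays labelled PAX3-FKHR-ER. Over the 186 probe sets called from replicates 2 and 3, the median change signed by its direction there was 0.06 in the replicate 1 pair labelled PAX3-FKHR-ER and 0.62 in the pair labelled pK1, a difference of 0.56, and 55.9% and 80.1% of them moved in that direction. That median was 0.02 and 0.03 in the pK1 pairs of replicates 2 and 3, with 55.4% and 56.5% moving so. By that median and share the replicate 1 pair labelled PAX3-FKHR-ER thus stood near those vector pairs. Single members still moved with the response in it, as GREM1 (0.81), CXCR4 (0.66), POU4F1 (0.55) and MYL11 (-1.02) did. Others moved against it, as MYOG (1.23), RASSF4 (0.78) and MYBPH (0.66) did. An exchange of construct labels within replicate 1 may be an explanation, with CXCR4 (2.20), ARRB1 (1.79) and STC1 (-1.04) among the members that moved that way in the pair labelled pK1, but it stays open, as MYOG (0.08), RASSF4 (0.73), PDE9A (-0.09), PRKAR2B (-0.36) and SYTL2 (-0.18) did not, and the log2 difference between constructs had an SD of 0.38 and 0.41 in replicate 1 against 0.51 to 0.79 in replicates 2 and 3, which an exchange alone would not shrink. A lower sensitivity of the replicate 1 arrays would leave both pairs under 50% of the change in replicates 2 and 3, and the larger one reached 60.7% (95% bootstrap interval 45.7 to 72.5 over probe sets, with no spread between pairs), which leaves it open too, although a loss shared by both pairs would not by itself set the pair labelled pK1 above the other. The probe sets were chosen on replicates 2 and 3, so their change there is likely overstated and the percent too low. It cannot decide the question. No sample was given another label, and a biological difference between populations of cells was not tested.

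Muscle genes were lower with 4-OHT in cells labelled PAX3-FKHR-ER of replicates 2 and 3, with a median log2 change of -0.54. An effect of 4-OHT apart from the fusion is argued against within replicates 2 and 3 by the camera test of the difference between constructs (adjusted p = 1.46e-05). However, that difference had adjusted p = 0.499 with an estimated correlation, and the replicate 1 medians were -0.24 labelled pK1 and -0.02 labelled PAX3-FKHR-ER. The array pK1 with 4-OHT replicate 2 had an actin ratio of 1.62 against 0.941 in its partner. That partner also left MYOG little room to fall, at 10.3 against 298 in PAX3-FKHR-ER without 4-OHT replicate 2. MYL11 was at 67.6 there against 2500. For such genes the control rests largely on pK1 replicate 3. Between-array scaling is argued against, as the median was -0.52 after quantile normalization. A change in RNA quality as read by the 3-prime over 5-prime control ratios is argued against, as these moved by -0.10 for actin in both replicates and by 0.04 and -0.03 for GAPDH, but the 18S 5-prime control, at 3175 against 548.9 in replicate 2 and 97.9 against 208 in replicate 3, leaves other changes of the RNA open. An action of the fusion on the muscle program may be an explanation too, as a hypothesis found and tested on the same 8 arrays.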

How the results depend on the processing

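The fits to replicates 2 and 3, and every setting tried on them, were chosen after seeing the data. The 22 alternative fits fixed beforehand, 10 other settings, the replicate block among them, and 12 that each left out 1 array, gave 0 probe sets past the threshold in limma in every comparison. The list results moved far more, and where a value changed side below the cause was not tested. With the replicate block on 12 arrays, no list called from 12 arrays without it was lost. Of the lists called from replicates 2 and 3 with the block, cell cycle and Notch and Wnt for 4-OHT in cells labelled PAX3-FKHR-ER, and targets (camera adjusted p = 0.696), interferon (0.240) and Notch and Wnt (0.696) for the difference between constructs, were not called with the block on 12 arrays.

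Probe sets past the threshold in replicates 2 and 3 with the replicate block numbered 106 higher and 80 lower for 4-OHT in cells labelled PAX3-FKHR-ER, 4 and 3 for the difference between constructs, 0 and 1 for the constructs without 4-OHT, and 17 and 4 with it. With no replicate block they numbered 0 and 0, 0 and 0, 0 and 1, and 11 and 2. For 4-OHT in cells labelled PAX3-FKHR-ER, pseudocount 0 gave 67 higher, no filter on signal 19 and 18 lower, only the 2 groups 303 and 233, and no trend 10 and 7. Of the 186, 124 were also called with pseudocount 0, 36 with no filter, 184 after quantile normalization, 17 with no trend and 186 with only the 2 groups. Of the 10 genes named each way by size of change, RASSF4, STC1 and SYTL2 lost their calls with pseudocount 0. With no filter these did too, as did GREM1, POU4F1, PDE9A, PRKAR2B, ING4, MYBPH, LINC00339, DUSP4 and IQSEC1. With no trend RASSF4, STC1, POU4F1, PRKAR2B, LDOC1, DUSP4 and IQSEC1 were lost. For the difference between constructs, pseudocount 64 gave 30 higher and 14 lower, quantile normalization 9 and 9, and no filter or no trend 0 and 0. For the constructs without 4-OHT, only the 2 groups gave 2 lower, and pseudocount 64, no filter, the 60% filter, quantile normalization and equal medians gave 0. For the constructs with 4-OHT, pseudocount 0 gave 2 and 0, pseudocount 64 gave 28 higher, no filter 3 and 1, the 60% filter 9 and 1, equal medians 11 higher, only the 2 groups 78 and 20, and no trend 1 and 1.

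For lists, adjusted p is from camera. For 4-OHT in cells labelled PAX3-FKHR-ER, the target call was lost with no filter (0.626) and the muscle call with the 60% filter (0.546), and both with an estimated correlation (adjusted p = 0.983). The direction of the fusion targets turned in pK1 cells within replicates 2 and 3 (0.949, and 0.927 with the replicate block), and in the difference between constructs with no filter (0.867); that of the interferon response turned there with the 60% filter (0.929). Some lists not called from 12 arrays passed in other settings. Heat shock genes in pK1 cells did so with the 60% filter (0.0218) and equal medians (0.0195). With only the 2 groups, the interferon response did for 4-OHT in cells labelled PAX3-FKHR-ER (0.0132) and between constructs with 4-OHT (0.0409), and cholesterol genes between constructs without it (0.0231). With array weights, muscle genes did in the difference between constructs (0.00483), interferon with 4-OHT (0.000592) and cholesterol without it (0.00183), the last also with pseudocount 64 (0.0488) and the mean of all probe sets of a gene (0.0169). The log2 change of PAX3 turned to -0.07 with array weights and to -0.26 in replicates 2 and 3, with and without the replicate block.

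For the constructs without 4-OHT, the myogenic regulators were lost with pseudocount 0 (0.0567), no filter (0.116), the 60% filter (0.236), quantile normalization (0.0789), equal medians (0.0644), no trend (0.0511), array weights (0.267) and in replicates 2 and 3 (0.261, and 0.218 with the replicate block). Heat shock genes were lost with no filter (0.0586), quantile normalization (0.535), no trend (0.0524), array weights (0.146), the mean of all probe sets of a gene (0.0630) and in replicates 2 and 3 (0.261, and 0.176 with the replicate block). Ribosomal proteins turned under quantile normalization (0.960) and were lost with array weights (0.267) and in replicates 2 and 3 (0.261, and 0.176 with the replicate block). Muscle genes were lost with no filter (0.0571). With an estimated correlation the adjusted p was 0.849 for targets, muscle, myogenic and ribosomal lists and 0.494 for heat shock. With 4-OHT, cholesterol genes were lost with no filter (0.0746), and they and the targets with an estimated correlation (adjusted p = 0.817).

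Leaving out 1 array at a time, which leaves 2 in its group and takes their spread from all groups, moved the adjusted p for 4-OHT in cells labelled PAX3-FKHR-ER from 0.000199 to 0.257 for targets (lost without PAX3-FKHR-ER without 4-OHT replicate 1 or with 4-OHT replicate 2). For muscle genes it ran from 1.91e-06 to 0.447 (lost without PAX3-FKHR-ER without 4-OHT replicate 2 or 3, or with 4-OHT replicate 1). It ran from 0.00166 to 0.991 for cell cycle, 0.342 to 0.981 for Notch and Wnt, and 0.0172 to 0.991 for interferon; the lows for cell cycle and interferon came without PAX3-FKHR-ER without 4-OHT replicate 1. Cell cycle turned without PAX3-FKHR-ER without 4-OHT replicate 2 (0.631), Notch and Wnt without PAX3-FKHR-ER with 4-OHT replicate 2 (0.929) and interferon without PAX3-FKHR-ER without 4-OHT replicate 3 (0.990). The targets in pK1 cells ran from 2.95e-05 (without pK1 with 4-OHT replicate 2) to 0.917 (without pK1 without 4-OHT replicate 2, turned), and without pK1 with 4-OHT replicate 1 they passed in the opposite direction (0.0415). Heat shock genes there ran from 0.0416 (without PAX3-FKHR-ER with 4-OHT replicate 1) to 0.339. For the difference between constructs the ranges were 2.59e-05 to 0.985 for targets, 4.44e-05 to 0.826 for muscle, 0.187 to 0.930 for Notch and Wnt, and 0.000246 to 0.941 for interferon. Interferon turned there without PAX3-FKHR-ER with 4-OHT replicate 1 (0.941) or without 4-OHT replicate 3 (0.798), without pK1 without 4-OHT replicate 1 (0.407) or 2 (0.582), and without pK1 with 4-OHT replicate 3, where it passed in the opposite direction (0.0350). Targets turned without PAX3-FKHR-ER with 4-OHT replicate 2 (0.903), pK1 without 4-OHT replicate 1 (0.596) and pK1 with 4-OHT replicate 2 (0.156) or 3 (0.873). Muscle turned without pK1 without 4-OHT replicate 2 (0.580) and with 4-OHT replicate 3 (0.485), and Notch and Wnt without those (0.851 and 0.822) and without PAX3-FKHR-ER with 4-OHT replicate 2 (0.903).

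Without 4-OHT the ranges between constructs were 0.000644 to 0.368 for targets and 1.99e-06 to 0.639 for muscle, both lost without replicate 2 of either construct. They were 0.00527 to 0.593 for myogenic regulators, lost without PAX3-FKHR-ER replicate 1 of either treatment or pK1 without 4-OHT replicate 2 or 3. They were 0.0223 to 0.289 for heat shock, lost without replicate 1 or 2 of either construct, and 6.67e-05 to 0.325 for ribosomal proteins, lost without PAX3-FKHR-ER replicate 2 or pK1 replicate 1. Cholesterol genes, called without 4-OHT with the replicate block (0.0162), ran from 0.000236 to 0.863 (without pK1 replicate 1). With 4-OHT the ranges were 2.08e-09 to 0.370 for targets, lost without replicate 2 of either construct. They were 1.53e-06 to 0.618 for cholesterol, lost without PAX3-FKHR-ER replicate 2 or 3 or pK1 replicate 1 or 3, and 0.000681 (without pK1 replicate 1) to 0.758 for interferon, which turned without pK1 replicate 3 (0.352). The log2 change of PAX3 with 4-OHT ran from -0.40 (without PAX3-FKHR-ER without 4-OHT replicate 1) to 0.53. The filter on mean signal over all arrays left out the dimmest probe sets, but some tested ones were dim in 1 group. In replicates 2 and 3 labelled PAX3-FKHR-ER, PDE9A read 5.97 without 4-OHT, and RASSF4 14.3 and MYBPH 14.6 with it. Signal over background limits the log2 change of such genes. In the paired fit that of RASSF4 went from -1.96 to -3.11 with pseudocount 0, where its limma adjusted p was 0.0958.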

Other observations

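The gene values below come from replicates 2 and 3, paired, a fit chosen only after the results were seen; the splits of the arrays were planned.

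Several secreted and matrix genes changed with 4-OHT in cells labelled PAX3-FKHR-ER without their lists moving 1 way. FST, which encodes follistatin, an inhibitor of activins, rose by 1.26 in log2 (limma adjusted p = 0.00808), while the TGF-beta and BMP list had a median of -0.17 (camera adjusted p = 0.742). FN1, fibronectin, rose by 1.12 (limma adjusted p = 0.00864), and TNC, tenascin C (-1.11, 0.00808), and LOXL1, a lysyl oxidase (-0.87, 0.0324), fell; of 34 matrix genes 1 rose and 2 fell (camera adjusted p = 0.742). IGFBP3, which binds insulin-like growth factors, fell (-1.25, limma adjusted p = 0.0228).

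Immediate early genes also went both ways there, and single members of stress lists rose. KLF4, a zinc finger transcription factor, rose by 1.14 (limma adjusted p = 0.00808) and JUN by 0.83 (0.0239), while DUSP4 fell, in a list of 16 immediate early genes with a camera adjusted p of 0.873. GADD45A, a gene induced by DNA damage, rose by 0.98 (limma adjusted p = 0.00864), and TRIB3, a pseudokinase of the amino acid response, by 0.96 (0.0221), each the 1 member past the threshold in lists that did not pass (camera adjusted p = 0.742 for p53 and apoptosis and 0.839 for the unfolded protein and amino acid response). ADM (0.76, limma adjusted p = 0.0262) and NDRG1 (0.84, 0.0408) of the hypoxia and glycolysis list rose too, and that list did not pass. NEFM, a neurofilament gene, fell (-0.86, limma adjusted p = 0.0188). No estrogen response gene of the 12 measured passed there (median -0.07, camera adjusted p = 0.742). Markers of other cells did not pass as lists either, with a median of -0.16 over 5 blood and endothelial genes (camera adjusted p = 0.984) and of -0.17 over 6 fibroblast and smooth muscle genes (0.288).

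Other splits of the same arrays were counted on all 12 arrays. For 4-OHT in cells labelled PAX3-FKHR-ER, 10 of the 10 splits gave as many probe sets (0, and 0 at most in the others) and 6 gave as many lists (2, and 6 at most). For pK1, 10 of 10 gave as many probe sets (0 and 0) and 10 as many lists (0, and 7 at most). For the constructs without 4-OHT, 10 of 10 gave as many probe sets (0 and 0) and 4 as many lists (5, and 7 at most). With 4-OHT, 10 of 10 gave as many probe sets (0 and 0) and 10 as many lists (2, and 7 at most). The other splits that part all pairs gave at most 2 lists for 4-OHT in cells labelled PAX3-FKHR-ER and 1 in pK1, but at most 6 for the constructs, both without and with 4-OHT. With 3 arrays against 3 there are too few splits for a share under 0.05. For the difference between constructs, 100 of 100 drawn splits gave as many probe sets (0, and 12 at most) and 100 as many lists (0, and 10 at most). Where the real count was 0 every split gives as many by construction, so those counts decide nothing about chance. What gave the higher counts in other splits was not tested.

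Between pairs of arrays, the 4-OHT changes over 13329 probe sets, which are not independent, had a Pearson r of 0.29 between replicates 2 and 3 labelled PAX3-FKHR-ER. For replicate 1 labelled pK1 against those pairs r was 0.23 and 0.21, and for replicate 1 labelled PAX3-FKHR-ER it was -0.01 and 0.01.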
